A study of Mus musculus with 7 samples.

How the data were processed

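Bulk RNA sequencing of kidney tissue from 4 MRL/lpr mice given AZD1152 and 3 given vehicle was analysed from the deposited table of raw read counts per gene. Per the labels' protocols, messenger RNA was enriched from total RNA with oligo(dT) beads, fragmented, copied with random primers, size-selected and amplified by PCR with a TruSeq RNA kit. Per the submitters' processing notes, bases were called with CASAVA, reads were aligned with HISAT2 2.0.5, the genome build was GRCm38, and DESeq2 and DESeq were also named. The counts were deposited by the authors as whole numbers without normalization. The read counter, its strand setting and the annotation release were not given in the sources used here, so reads of overlapping or antisense genes could not be told apart. Nothing in the labels gave a sequencing batch or date, the dose, the schedule or the age of the mice.

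Groups and replicate numbers were taken from the sample titles, and the series text says that the libraries came from separate mice. All 7 columns of the table were used. Of 53465 genes in the table, 53274 had a name in GENCODE mouse release 21 (GRCm38), which also gave coordinates, exon overlaps, GC content and length. The deposited counts of no 2 libraries agreed within sampling noise, as the lowest chi-square per degree of freedom over 21 pairs was 10.8. The labels number the mice of both groups, but the numbers say nothing of shared litters or days, and the groups hold different mice.

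Library totals ran from 14692113 to 17036862 counts, and 3 counts, the floor used for a gene with 0 counts, correspond to 0.176 to 0.204 CPM. PCR reads without molecular identifiers are not independent molecules, so this floor covers counting error only. Counts were filtered with filterByExpr, scaled with TMM and tested in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood test on group alone. Adjusted p-values are Benjamini-Hochberg values over 15774 genes with a threshold of 0.05, two-sided. Standard errors were taken as the size of the log2 fold change divided by the square root of the F statistic. CPM are TMM-scaled counts for each library total, and log2 CPM of single libraries used a prior count of 2. The biological coefficient of variation from the common dispersion was 0.168.

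34 gene lists were fixed before the data were examined, as were the groups, the tests, the rule for named genes and all alternatives except those said below to be added. 6 were primary lists (mitosis, type I interferon response, B and plasma cells, T cells, macrophages and proximal tubule). The other 28 covered DNA replication, p53 targets, cytotoxic lymphocytes, neutrophils, MHC class I and class II presentation, chemokines, inflammatory cytokines and NF-kB targets, complement, tubular injury, extracellular matrix and fibrosis, podocytes, endothelium, loop of Henle, distal convoluted tubule, collecting duct, fatty acid oxidation, oxidative phosphorylation, cholesterol synthesis, unfolded protein response, immediate early genes, circadian clock, erythroid cells, perirenal fat, adrenal cortex, skeletal muscle, Y-linked and X-inactivation genes, and androgen-dependent kidney genes. Of 541 list genes 540 matched a gene of the table, 1 of them through a synonym. Lists were tested with the directional p of fry (limma 3.58.1), adjusted over the 34 lists by Benjamini-Hochberg. Fry asks whether the genes of a list move one way on balance and does not compare the list with other genes. Of 34 lists 20 were called by fry, 23 by camera with a preset correlation of 0.01 and 0 by camera with an estimated correlation, where 8 had an unadjusted p under 0.05.

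Named genes were the 4 genes of the chromosomal passenger complex, the 12 largest rises and 12 largest falls, and the members of each list with the smallest p, up to 4 in a primary and up to 3 in a secondary list, and the Y-linked and X-inactivation genes as a check of sex. The largest changes were taken among called genes with a mean of at least 2 CPM and no overlap between the groups, without immunoglobulin and T cell receptor segments, pseudogenes and genes with Gm, Rik, AC, AL, BC or LOC names, from a pool of 1106 genes. The text leaves out 3 genes that the rule would name. The steps were tested on simulated counts with 200 changed genes in 5 runs over 15552 genes for the comparison of AZD1152 with vehicle. They recovered 30.7% of genes changed 1.5-fold, 72.5% of those changed 2-fold and 92.7% of those changed 4-fold, with 8.81% false calls. They found a mitosis list lowered 2-fold in 5 of 5 runs, and called 0 lists where only the 200 genes were changed. Each gene was simulated independently of the others. The list results therefore do not tell how often lists of genes that move together are called falsely.

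The alternatives were RLE and upper-quartile factors, TMM factors without immunoglobulin, mitochondrial and the 50 most abundant genes, no filter on low counts, a stricter filter (a CPM of 1 in 3 libraries and a mean CPM of 2), DESeq2 1.42.0, limma-voom with sample weights, the replicate number as a block over 6 libraries, each library left out, an adjusted p under 0.1, and a log2 fold change above 1 in size. Scaling by total counts was added after the data were seen, as were upper-quartile factors and the stricter filter for the primary lists and the scaling, filter and preset-correlation fits for the secondary lists. Score tests were exact permutation tests of group means over the 35 splits of the libraries (R 4.3.3), two-sided, with a smallest p of 0.0286. The trend of the log2 fold change on GC content, length and expression was removed with loess fits over all genes with a GC value, first on GC content and length and then on mean CPM. Figures were drawn with matplotlib 3.10.9.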

Results

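Kidney RNA was sequenced from 7 MRL/lpr mice, a strain with a defective Fas gene that develops a spontaneous lupus-like disease with nephritis. 4 mice had received AZD1152 (barasertib), a prodrug whose active form inhibits Aurora kinase B, and 3 had received vehicle. Aurora kinase B is the catalytic subunit of the chromosomal passenger complex, which acts in chromosome segregation and cytokinesis. Each mouse gave 1 poly(A)-selected library, and the values were read counts per gene. Library totals were 16581099, 16930859 and 16195173 counts for vehicle replicates 1 to 3. They were 17036862, 16366632, 16130751 and 14692113 counts for AZD1152 replicates 1 to 4. All libraries held between 9842 and 15280 counts of Xist, the RNA that silences an X chromosome in female cells. The Y-linked genes Kdm5d, Eif2s3y and Uty had 0 counts, which allows up to 0.204 CPM in the shallowest library, and Ddx3y had 3 counts over all libraries. By these counts all 7 mice were female. Transcripts of the mitochondrial genome took 8.03% to 9.0% of the counts in vehicle kidneys and 9.41% to 11.6% in AZD1152 kidneys. The 10 genes with most counts took 11.6% to 13.0% and 14.4% to 16.7%, and AZD1152 replicate 2 was the highest of the 7 libraries in both measures.

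The comparison of AZD1152 with vehicle asked how the renal transcriptome of lupus-prone mice differed with treatment. Inhibition of the kinase itself was not measured here. In the treated kidneys, genes of mitosis, interferon-induced genes, chemokines, T cell and macrophage markers and markers of tubular injury fell as lists in fry, and genes of the proximal tubule, the distal convoluted tubule, the collecting duct and oxidative phosphorylation rose. Of the 34 lists fry called 20, and camera called 0 with an estimated correlation, where the 20 had adjusted p = 0.132 to 0.231. Of 15774 genes tested, 476 were higher and 759 were lower in AZD1152 kidneys at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test, so that 38.5% of the calls were higher. Among them, 390 lower and 38 higher genes changed by more than 1 on the log2 scale. The first principal component held 41.7% of the variance, with vehicle libraries at -46.2 to -22.7 and AZD1152 libraries at 5.3 to 47.1. Scaling by total counts in place of TMM moved the median log2 fold change of all genes to -0.151 and gave 232 higher and 1482 lower genes, with 13.5% of the calls higher. The counts fell most without vehicle replicate 3 (60 higher and 163 lower), vehicle replicate 1 (126 and 272) and AZD1152 replicate 4 (107 and 336). They were 229 and 521 without AZD1152 replicate 2, 248 and 608 without AZD1152 replicate 3, and 311 and 582 without AZD1152 replicate 1.

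Aurkb, which encodes the target of the drug, fell in the treated kidneys, and so did Birc5 (survivin) and Incenp, its partners in the complex. Markers of T cells and macrophages fell with them, with a mean score lower by 1.18 ± 0.196 on the log2 scale (SE). Aurkb (ENSMUSG00000020897; GRCm38 chromosome 11, 69045647 to 69051664, plus strand) averaged 2.74 ± 0.649 CPM (SD, n = 3) with vehicle and 1.01 ± 0.267 CPM (SD, n = 4) with AZD1152. Its log2 fold change was -1.44 ± 0.29 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0234). Birc5 (ENSMUSG00000017716; chromosome 11, 117849251 to 117855743, plus strand) went from 2.76 ± 0.375 to 1.14 ± 0.117 CPM, a log2 fold change of -1.26 ± 0.22 (edgeR adjusted p = 0.0174). Incenp (ENSMUSG00000024660; chromosome 19, 9872296 to 9899551, minus strand), the scaffold of the complex, went from 8.56 ± 1.20 to 5.10 ± 0.498 CPM. Its log2 fold change was -0.75 ± 0.16 (edgeR adjusted p = 0.0272). Cdca8 (borealin; ENSMUSG00000028873; chromosome 4, 124918465 to 124939311, minus strand) had 2.05 ± 0.256 and 1.36 ± 0.476 CPM and did not pass the test (log2 fold change -0.60 ± 0.31, edgeR adjusted p = 0.277). It shares exonic positions with 9930104L06Rik. The Aurkb call was lost without vehicle replicate 1, 2 or 3 (edgeR adjusted p = 0.0545, 0.0559 and 0.0683), and the Birc5 call without vehicle replicate 1 or 3 (0.0598 and 0.0675). The Incenp call was lost without vehicle replicate 2 or 3 or AZD1152 replicate 1, 2 or 4 (edgeR adjusted p = 0.0585, 0.11, 0.0524, 0.0552 and 0.0634).

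**Figure D1:**
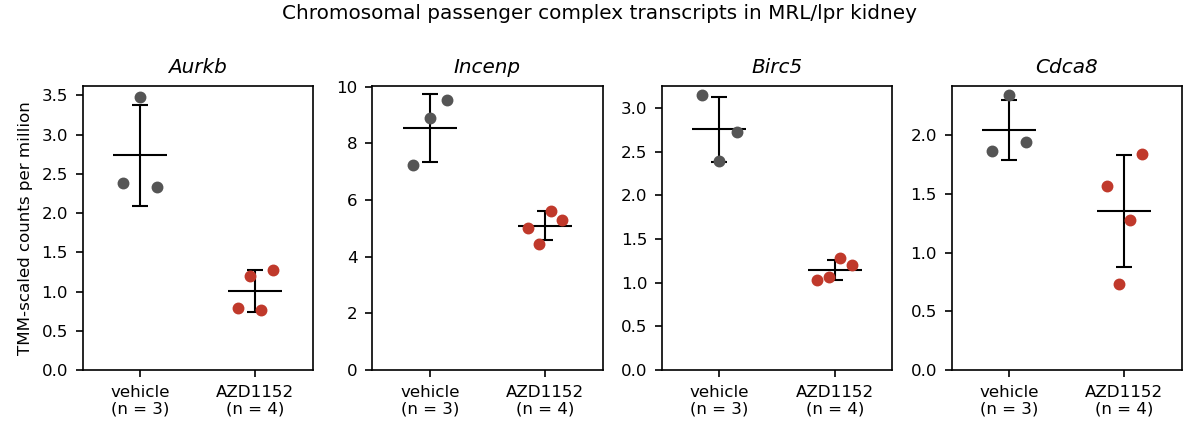
TMM-scaled CPM (vertical axes, each starting at 0) of the 4 transcripts of the chromosomal passenger complex in 3 vehicle (grey) and 4 AZD1152 (red) kidneys; points are libraries, horizontal lines group means and bars 1 SD. Aurkb averaged 2.74 CPM with vehicle and 1.01 CPM with AZD1152, and no AZD1152 point of the 4 genes reached a vehicle point, although Cdca8 did not pass the test.

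Genes that act in mitosis fell as a list in the treated kidneys, with a mean score lower by 1.08 ± 0.162 on the log2 scale (SE) beside 1.18 ± 0.196 for markers of T cells and macrophages. The mitosis score minus that of these markers differed by 0.098 ± 0.134 (SE), within its spread. All 34 members of the mitosis list had negative estimates, with a median log2 fold change of -1.13. Of these, 16 fell over all genes and 28 when adjusted over the list alone, and fry called the list (Benjamini-Hochberg adjusted p = 0.00617; adjusted p = 0.14 with an estimated correlation). Ccnb1 and Ccnb2, which encode cyclins that drive entry into mitosis, fell by 2.06 ± 0.32 and 1.57 ± 0.25 on the log2 scale (SE; edgeR adjusted p = 0.0125 and 0.0128). Mki67, the proliferation marker Ki-67, fell from 19.3 ± 0.825 to 7.52 ± 2.16 CPM, and Cenpe, a kinetochore motor, from 3.68 ± 0.524 to 1.49 ± 0.245 CPM (edgeR adjusted p = 0.0113 and 0.0149). Genes of DNA replication had a median of -0.32 over 25 measured members, and 2 fell over all genes and 6 when adjusted over the list alone (fry adjusted p = 0.0231; adjusted p = 0.17 with an estimated correlation). Those 2 were Mcm3, a subunit of the replicative helicase (-0.73 ± 0.17), and Lig1, a DNA ligase gene that shares exonic positions with Zswim9 (-0.68 ± 0.16), with edgeR adjusted p = 0.0347 and 0.0364. Rrm2, a subunit of ribonucleotide reductase, had a log2 fold change of -0.73 ± 0.19 (edgeR adjusted p = 0.0512). The list of 20 p53 targets was not called (median -0.20, fry adjusted p = 0.122), and 2 members fell over all genes and 2 when adjusted over the list alone. Cdkn1a, which encodes the inhibitor of cyclin-dependent kinases p21, fell by 1.14 ± 0.20 and Trp53inp1 by 0.37 ± 0.09 on the log2 scale, while Mdm2 had -0.19 ± 0.08 (edgeR adjusted p = 0.0175, 0.0369 and 0.16). The mitosis list stayed called without any 1 of the 7 libraries, and the DNA replication call was lost without vehicle replicate 3 (fry adjusted p = 0.0711). Without vehicle replicate 3 the calls of Ccnb1 and Cenpe were lost, that of Cdkn1a without vehicle replicate 1 or 3, and those of Trp53inp1, Lig1 and Mcm3 without 6, 6 and 7 of the 7 libraries (edgeR adjusted p up to 0.0562, 0.0683, 0.0723, 0.126, 0.148 and 0.0892).

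Interferon-induced genes fell in the treated kidneys. All 30 members of the type I interferon list had negative estimates, with a median log2 fold change of -0.96, and 21 fell over all genes and 24 when adjusted over the list alone. Fry called the list (adjusted p = 0.00617; adjusted p = 0.132 with an estimated correlation). Oasl2, of the oligoadenylate synthetase family, fell from 48.7 ± 4.99 CPM (SD, n = 3) to 17.5 ± 2.52 CPM (SD, n = 4), a log2 fold change of -1.48 ± 0.13 (edgeR adjusted p = 0.00374). Irf7, a transcription factor that amplifies interferon production, fell from 70.1 ± 11.9 to 32.9 ± 3.19 CPM. Ifi44 and Stat2, the latter a transducer of interferon receptor signals, fell by 0.99 ± 0.12 and 0.75 ± 0.10 on the log2 scale. The calls of the list and of these 4 genes held without any 1 of the 7 libraries. Genes of MHC class I presentation fell, 10 of 12 over all genes and 12 when adjusted over the list alone, with a median of -0.97 (fry adjusted p = 0.0273; adjusted p = 0.17 with an estimated correlation). Psmb10 and Psme2, of the immunoproteasome and its activator, fell by 1.15 ± 0.16 and 0.54 ± 0.08, and Nlrc5, the transactivator of class I genes, by 1.33 ± 0.23 on the log2 scale. In the list for MHC class II presentation 4 of 11 members fell over all genes and 10 when adjusted over the list alone, with a median of -1.02 (fry adjusted p = 0.0307; adjusted p = 0.17 with an estimated correlation). Macrophage and T cell markers fell with them, with medians of -0.96 and -1.41. Ctss, the protease that trims the invariant chain, fell from 256.6 ± 44.2 to 120.1 ± 32.2 CPM. H2-Eb1 fell by 1.02 ± 0.22 and Ciita, the class II transactivator, by 1.29 ± 0.28 on the log2 scale. Irf7, Nlrc5 and Ciita share exonic positions with Phrf1, 9330175E14Rik and Dexi, and the Oas and H2 families hold near-identical members, so their values depend on how shared reads were assigned. The class I call was lost without vehicle replicate 1 or 3 or AZD1152 replicate 1 (fry adjusted p = 0.0603, 0.0711 and 0.0558), and the class II call without each library except AZD1152 replicate 3 (fry adjusted p = 0.0535 to 0.091). The Nlrc5 call was lost without vehicle replicate 3, that of Ctss without vehicle replicate 1 or 3, and those of H2-Eb1 and Ciita without any vehicle replicate or AZD1152 replicate 1 (edgeR adjusted p up to 0.0597, 0.062, 0.0834 and 0.0748).

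Lists of chemokines and inflammatory transcripts fell with AZD1152, and so did those of T cells, cytotoxic lymphocytes and macrophages (medians -1.41, -1.30 and -0.96). Ccl5 is in both the chemokine and the cytotoxic list, and C1qa in both the complement and the macrophage list. The chemokine list had a median log2 fold change of -1.56 over 14 measured members, of which 8 fell over all genes and 13 when adjusted over the list alone (fry adjusted p = 0.00617; adjusted p = 0.132 with an estimated correlation). Ccl5, a T cell and macrophage attractant, fell from 36.3 ± 9.11 to 9.27 ± 2.81 CPM. Ccl2 and Ccl7, which recruit monocytes, fell by 1.92 ± 0.32 and 2.11 ± 0.32 on the log2 scale (edgeR adjusted p = 0.014 and 0.0121). The list of inflammatory cytokines and NF-kB targets had 9 of 15 measured members lower over all genes and 14 when adjusted over the list alone, with a median of -0.84 (fry adjusted p = 0.00617; adjusted p = 0.135 with an estimated correlation). Vcam1, an adhesion molecule for leukocytes, fell from 146.2 ± 18.3 to 47.0 ± 13.2 CPM. Tnfaip3 and Nfkbia, feedback inhibitors of NF-kB, fell by 1.10 ± 0.13 and 0.70 ± 0.10 on the log2 scale. The calls of both lists held without any 1 of the 7 libraries. In the complement list 5 of 13 members fell and 1 rose over all genes, and 8 fell and 1 rose when adjusted over the list alone, with a median of -0.66 (fry adjusted p = 0.0307; adjusted p = 0.17 with an estimated correlation). C3, the central component, fell from 543.7 ± 118.3 to 224.3 ± 65.2 CPM, and C1qa, of the classical pathway, from 163.5 ± 5.61 to 85.5 ± 23.0 CPM. Cfb, which encodes factor B of the alternative pathway, rose from 8.14 ± 0.766 to 14.3 ± 0.934 CPM (edgeR adjusted p = 0.0107). The complement call was lost without each library except AZD1152 replicate 3 (fry adjusted p = 0.062 to 0.0968). The calls of Ccl2, C1qa and C3 were lost without vehicle replicate 3, that of C1qa also without vehicle replicate 1 and that of C3 also without AZD1152 replicate 4 (edgeR adjusted p up to 0.0562, 0.0795 and 0.0834).

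Markers of T cells, cytotoxic lymphocytes and macrophages fell in the treated kidneys, and those of B and plasma cells and of neutrophils were not called. The T cell list had a median log2 fold change of -1.41, with 13 of 22 measured members lower over all genes and 20 when adjusted over the list alone (fry adjusted p = 0.0285; adjusted p = 0.17 with an estimated correlation). Lat, an adaptor of the T cell receptor, fell from 8.0 ± 1.58 to 2.35 ± 0.355 CPM. Cd3g and Cd3d, which encode chains of the receptor complex, fell by 1.51 ± 0.25 and 1.36 ± 0.27, and Lck, its kinase, by 1.49 ± 0.26 on the log2 scale. The list of cytotoxic lymphocytes had 6 of 11 measured members lower over all genes and 11 when adjusted over the list alone, with a median of -1.30 (fry adjusted p = 0.0231; adjusted p = 0.17 with an estimated correlation). Gzmk and Gzmb, granzymes of cytotoxic cells, fell by 2.15 ± 0.33 and 2.06 ± 0.35 on the log2 scale. The macrophage list had a median of -0.96, with 12 of 22 members lower over all genes and 20 when adjusted over the list alone (fry adjusted p = 0.0285; adjusted p = 0.17 with an estimated correlation). Fcgr1, an activating Fc receptor, fell from 19.3 ± 0.758 to 6.36 ± 2.21 CPM and Lyz2 (lysozyme) from 412.1 ± 127.8 to 188.0 ± 35.5 CPM. Tyrobp, a signalling adaptor, and Aif1 fell by 1.07 ± 0.20 and 1.22 ± 0.23 on the log2 scale. The list for B and plasma cells had a median of -0.83 (fry adjusted p = 0.25). In edgeR 0 of its 24 measured members passed, over all genes or adjusted over the list alone, with 7 at an unadjusted p under 0.05 and 3 called by DESeq2. Cd22, Prdm1, Cd79b and Sdc1 had log2 fold changes of -0.76 ± 0.21, -0.61 ± 0.18, -1.09 ± 0.36 and -0.55 ± 0.20. In edgeR 0 of 9 measured neutrophil genes passed, over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 1 called by DESeq2 (median -0.32, fry adjusted p = 0.25). Csf3r, Mmp9 and S100a8 had -0.74 ± 0.25, -0.90 ± 0.39 and -1.01 ± 0.50. The T cell call was lost without vehicle replicate 2 or 3 or AZD1152 replicate 1, 2 or 4 (fry adjusted p = 0.0535 to 0.0909), the cytotoxic call without vehicle replicate 3 or AZD1152 replicate 1 or 4 (0.0547 to 0.0711), and the macrophage call without vehicle replicate 1 or 3 or AZD1152 replicate 1 or 2 (0.0535 to 0.0795). The calls of Cd3g, Lck, Gzmb, Lyz2, Cd3d and Tyrobp were lost without vehicle replicate 3, that of Cd3d also without vehicle replicate 2 or AZD1152 replicate 4 and that of Tyrobp also without vehicle replicate 1 (edgeR adjusted p up to 0.0583, 0.0551, 0.0532, 0.0524, 0.0835 and 0.0689).

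**Figure D2:**
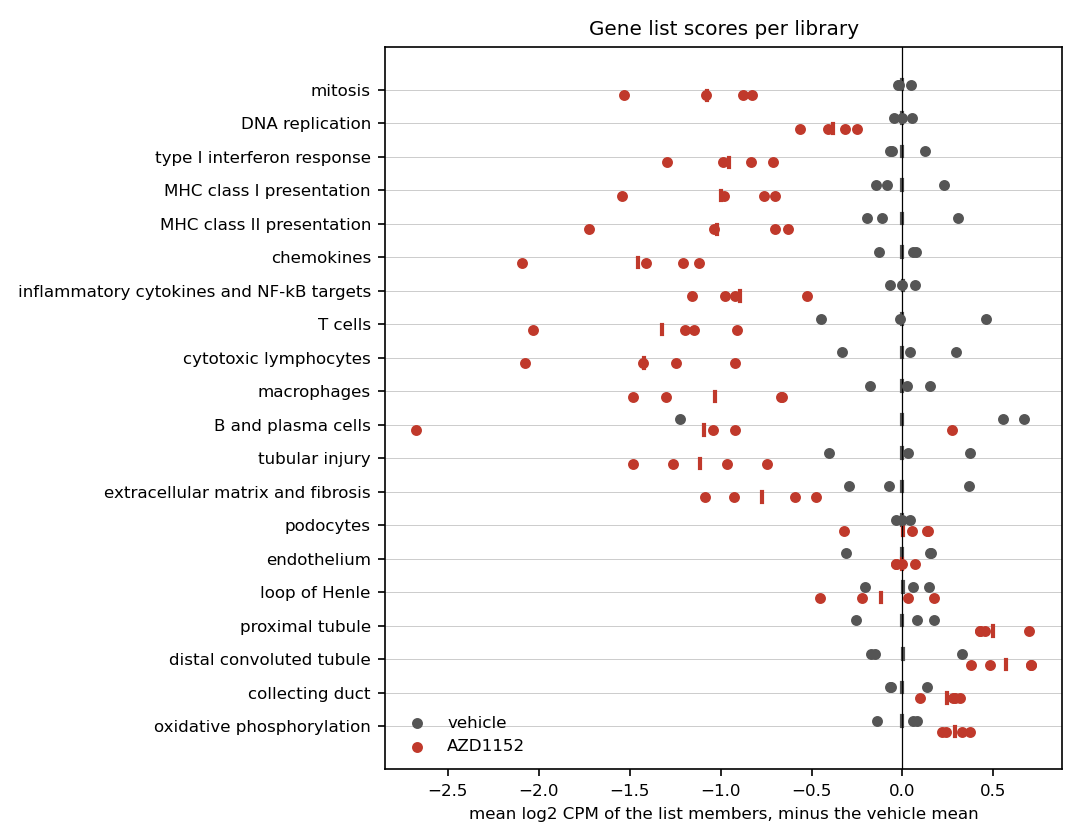
Mean log2 CPM of the measured members of 20 gene lists in each library, minus the mean of the 3 vehicle libraries (horizontal axis, log2 units), with vehicle in grey and AZD1152 in red; points are libraries and short vertical bars group means. The 4 AZD1152 libraries lay below the 3 vehicle libraries for mitosis (-1.53 to -0.82 against -0.03 to 0.05), above them for the proximal tubule (0.42 to 0.70 against -0.26 to 0.18), and on both sides of the lowest vehicle library for B and plasma cells (-2.67 to 0.28 against -1.22 to 0.67, with 3 of the 4 within the vehicle range).

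The lists of tubular injury and of the extracellular matrix fell, and so did markers of macrophages and T cells (medians -0.96 and -1.41). Vcam1, Cd44 and Timp1 of these lists are also made by leukocytes or stromal cells. In the tubular injury list 9 of 17 members fell over all genes and 13 when adjusted over the list alone, with a median log2 fold change of -0.87 (fry adjusted p = 0.0285; adjusted p = 0.17 with an estimated correlation). Beside Vcam1, its members with the smallest p were Cd44, a hyaluronan receptor, and Cp (ceruloplasmin). Cd44 fell from 36.0 ± 9.52 to 12.7 ± 2.40 CPM and Cp, which shares exonic positions with Hps3, from 199.2 ± 62.7 to 90.2 ± 15.7 CPM (edgeR adjusted p = 0.00951 and 0.0175). The extracellular matrix list had 4 of 18 measured members lower over all genes and 9 when adjusted over the list alone, with a median of -0.67 (fry adjusted p = 0.042; adjusted p = 0.174 with an estimated correlation). Col1a1, a chain of type I collagen, fell from 79.4 ± 21.9 to 32.1 ± 9.97 CPM. Timp1, an inhibitor of metalloproteinases, and Tgfb1, a profibrotic cytokine, fell by 2.23 ± 0.41 and 0.65 ± 0.13 on the log2 scale. Without vehicle replicate 1 or 3 or AZD1152 replicate 1, 2 or 4 the calls of both lists were lost (fry adjusted p = 0.0535 to 0.0795 for tubular injury and 0.0775 to 0.112 for matrix). The calls of Timp1, Col1a1 and Tgfb1 were lost without vehicle replicate 1 or 3, those of Col1a1 and Tgfb1 also without AZD1152 replicate 4, and that of Cp without AZD1152 replicate 4 (edgeR adjusted p up to 0.0773, 0.0768, 0.0882 and 0.0502).

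Transcripts of the proximal tubule, the distal convoluted tubule and the collecting duct rose in the treated kidneys, and those of the loop of Henle, podocytes and endothelium were not called. All 24 members of the proximal tubule list had positive estimates, with a median log2 fold change of 0.54, and 9 rose over all genes and 15 when adjusted over the list alone (fry adjusted p = 0.0285; adjusted p = 0.17 with an estimated correlation). After removal of the trend on GC content, length and expression over all genes the median was 0.27. Slc34a1, the main phosphate transporter of this segment, rose from 3108 ± 638.3 CPM (SD, n = 3) to 4961 ± 329.7 CPM (SD, n = 4). Fbp1, a gluconeogenic enzyme, rose from 907.9 ± 138.4 to 1478 ± 118.4 CPM. Slc5a2, the glucose transporter SGLT2, and Slc5a12, a lactate transporter, rose by 0.75 ± 0.14 and 0.81 ± 0.17 on the log2 scale. Slc5a2 shares exonic positions with BC017158. The distal convoluted tubule list had 3 of 7 members higher over all genes and 5 when adjusted over the list alone, with a median of 0.63 (fry adjusted p = 0.0307; adjusted p = 0.17 with an estimated correlation). Klhl3 rose by 0.51 ± 0.08, the calcium-binding Pvalb by 0.93 ± 0.22 and the magnesium channel Trpm6 by 0.63 ± 0.15 on the log2 scale. The collecting duct list had 4 of 11 measured members higher over all genes and 5 when adjusted over the list alone, with a median of 0.29 (fry adjusted p = 0.0285; adjusted p = 0.17 with an estimated correlation), or 0.19 after removal of that trend. Scnn1g, a subunit of the epithelial sodium channel, rose by 0.44 ± 0.10, the anion exchanger Slc26a4 by 0.51 ± 0.12 and Hsd11b2, which inactivates glucocorticoids, by 0.29 ± 0.07 on the log2 scale. In these kidneys the mitochondrial share of counts and the share of the 10 most abundant genes were also higher, at 9.41% to 11.6% and 14.4% to 16.7%. Among 9 genes of the loop of Henle, 15 of podocytes and 12 of endothelium 0 passed in edgeR, over all genes or adjusted over the list alone (medians -0.11, 0.04 and -0.02; fry adjusted p = 0.761, 0.935 and 0.96). Of these, 1, 4 and 1 had an unadjusted p under 0.05, and DESeq2 called 0, 1 and 0. The endothelium list had a negative median and mean and a positive direction in fry. Cldn16, Egf and Umod of the loop of Henle list had log2 fold changes of -0.37 ± 0.16, 0.28 ± 0.15 and -0.33 ± 0.23, and Egf shares exonic positions with Gm42697. The podocyte genes Magi2 and Cdkn1c had 0.51 ± 0.16 and -0.54 ± 0.21, and the endothelial genes Flt1, Pecam1 and Kdr 0.33 ± 0.13, -0.23 ± 0.15 and 0.12 ± 0.09. The proximal tubule and collecting duct calls were lost without vehicle replicate 1 or 3 or AZD1152 replicate 1, 2 or 4 (fry adjusted p = 0.0535 to 0.0795 and 0.062 to 0.0968), and the distal convoluted tubule call without each library except vehicle replicate 2 (0.0535 to 0.101). With scaling by total counts the distal convoluted tubule and collecting duct lists lost their calls (fry adjusted p = 0.0901 and 0.158), as did Trpm6, Scnn1g, Slc26a4 and Hsd11b2, and the podocyte and endothelium lists and Kdr turned negative. The calls of Klhl3 and Fbp1 held without any 1 library, and those of Slc5a2 and Slc5a12 were lost without vehicle replicate 1 or 3 or AZD1152 replicate 4 (edgeR adjusted p up to 0.0662 and 0.0689). Those of Slc34a1, Pvalb, Trpm6, Scnn1g, Slc26a4 and Hsd11b2 were lost without 5 or 6 of the 7 libraries, vehicle replicates 1 and 3 and AZD1152 replicate 4 among them (edgeR adjusted p up to 0.0923, 0.114, 0.159, 0.101, 0.133 and 0.142).

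Lists of genes of mitochondrial energy metabolism were called higher, and so were those of the proximal and the distal convoluted tubule (medians 0.54 and 0.63). In the oxidative phosphorylation list 6 of 22 nuclear-encoded members rose over all genes and 17 when adjusted over the list alone, with a median log2 fold change of 0.31 (fry adjusted p = 0.0285; adjusted p = 0.231 with an estimated correlation). That median was 0.05 after removal of the trend on GC content, length and expression over all genes, and the mean went from 0.286 to 0.137 with scaling by total counts. Ndufa9, of complex I, and Uqcrc2, of complex III, rose by 0.40 ± 0.08 and 0.40 ± 0.10 on the log2 scale. The fatty acid oxidation list had 3 of 20 members higher over all genes and 7 when adjusted over the list alone, with a median of 0.39 (fry adjusted p = 0.0352; adjusted p = 0.174 with an estimated correlation). Acaa2, a thiolase of mitochondrial beta-oxidation, rose from 164.9 ± 14.1 to 274.4 ± 25.6 CPM. Acadvl and Hadhb, of the same pathway, rose by 0.37 ± 0.07 and 0.39 ± 0.08 on the log2 scale (edgeR adjusted p = 0.0206 and 0.0241). Transcripts of the mitochondrial genome took 8.03% to 9.0% of the counts with vehicle and 9.41% to 11.6% with AZD1152. Acadvl and Uqcrc2 share exonic positions with Dvl2 and Pdzd9, and their calls were lost with scaling by total counts, as was that of the fatty acid oxidation list (fry adjusted p = 0.18). The oxidative phosphorylation call was lost without vehicle replicate 1 or 3 or AZD1152 replicate 1, 2 or 4 (fry adjusted p = 0.0537 to 0.0711), and the fatty acid oxidation call without each library except AZD1152 replicate 3 (0.0556 to 0.105). The calls of Ndufa9, Acadvl and Hadhb were lost without vehicle replicate 1 or 3 or AZD1152 replicate 4, and that of Uqcrc2 whichever of the 7 was left out (edgeR adjusted p up to 0.082, 0.0673, 0.0802 and 0.131).

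The 12 largest rises by the rule for named genes were picked by their fold change. Dnase1, which encodes a secreted nuclease that degrades extracellular DNA (ENSMUSG00000005980; chromosome 16, 4036942 to 4040024, plus strand), rose from 28.9 ± 9.18 to 114.2 ± 35.6 CPM. Its log2 fold change was 1.99 ± 0.28 (edgeR adjusted p = 0.0107), and it shares exonic positions with Trap1 and Gm15879. Hpd, an enzyme of tyrosine breakdown, rose from 99.7 ± 26.6 to 314.4 ± 97.2 CPM, and Pde6a, a phosphodiesterase subunit, from 1.68 ± 0.624 to 5.81 ± 1.31 CPM (edgeR adjusted p = 0.0138 and 0.0149). The acetyltransferase genes Nat8f3, Nat8f7 and Nat8f6 rose by 1.39 ± 0.21, 1.77 ± 0.29 and 1.42 ± 0.29 on the log2 scale. The carboxylesterase genes Ces1d and Ces1e rose by 1.33 ± 0.25 and 1.46 ± 0.31, and the transporter genes Slc22a28 and Slc22a30 by 1.68 ± 0.36 and 1.38 ± 0.34. These families hold near-identical members that can share reads, and Nat8f6 also shares exonic positions with Nat8f5. Nepn and Marc1 rose by 1.35 ± 0.28 and 1.56 ± 0.39. The calls of Dnase1, Nat8f3, Nat8f7 and Pde6a held without any 1 of the 7 libraries. Those of Hpd, Ces1d, Nepn, Ces1e, Nat8f6, Slc22a28, Slc22a30 and Marc1 were lost without 1, 1, 3, 3, 4, 4, 6 and 7 libraries, vehicle replicate 3 always among them (edgeR adjusted p up to 0.0532, 0.0873, 0.103, 0.11, 0.0845, 0.119, 0.163 and 0.153). The Marc1 call was also lost with scaling by total counts, and those of Marc1, Slc22a28 and Slc22a30 with limma-voom.

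The 12 largest falls were picked in the same way. Krt20, a keratin, had a log2 fold change of -4.34 ± 0.90 and Marco, a macrophage scavenger receptor, of -4.10 ± 0.98 (edgeR adjusted p = 0.026 and 0.0393). In vehicle replicates 1 to 3 Krt20 had 5.88, 2.06 and 22.2 CPM and Marco 26.2, 1.09 and 4.22 CPM, against at most 1.28 and 0.958 CPM in any AZD1152 kidney. Ubd, a ubiquitin-like modifier induced by cytokines, fell from 92.3 ± 34.3 to 14.3 ± 7.67 CPM, and Cxcl1, a neutrophil chemokine, from 6.62 ± 3.42 to 1.10 ± 0.683 CPM. Ccl8, another chemokine, fell from 32.8 ± 9.68 to 7.74 ± 3.69 CPM, and Aoc1, a diamine oxidase, from 32.1 ± 15.95 to 7.87 ± 3.11 CPM. Siglec1, an interferon-induced receptor of macrophages, fell from 20.4 ± 7.41 to 5.14 ± 0.813 CPM (edgeR adjusted p = 0.00951). H2-Eb2, a class II gene, and Adam8, a metalloproteinase, fell by 2.14 ± 0.46 and 2.12 ± 0.36 on the log2 scale, and Timp1, Gzmk and Gzmb completed the 12. The calls of Siglec1, Gzmk and Ccl8 held without any 1 of the 7 libraries, and those of Gzmb, Adam8 and Ubd were lost without vehicle replicate 3 (edgeR adjusted p = 0.0532, 0.0621 and 0.056). Those of Timp1, Aoc1, Cxcl1 and H2-Eb2 were lost without vehicle replicate 1 or 3, those of Aoc1, Cxcl1 and H2-Eb2 also without AZD1152 replicate 4, and that of H2-Eb2 also without vehicle replicate 2 (edgeR adjusted p up to 0.0773, 0.0753, 0.0814 and 0.0704). The Krt20 call was lost without 5 libraries, with -3.00 without vehicle replicate 3 (edgeR adjusted p = 0.0929), and the Marco call without each library except vehicle replicate 2, with -2.12 without vehicle replicate 1 (edgeR adjusted p = 0.102). Both were also lost with limma-voom.

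**Figure D3:**
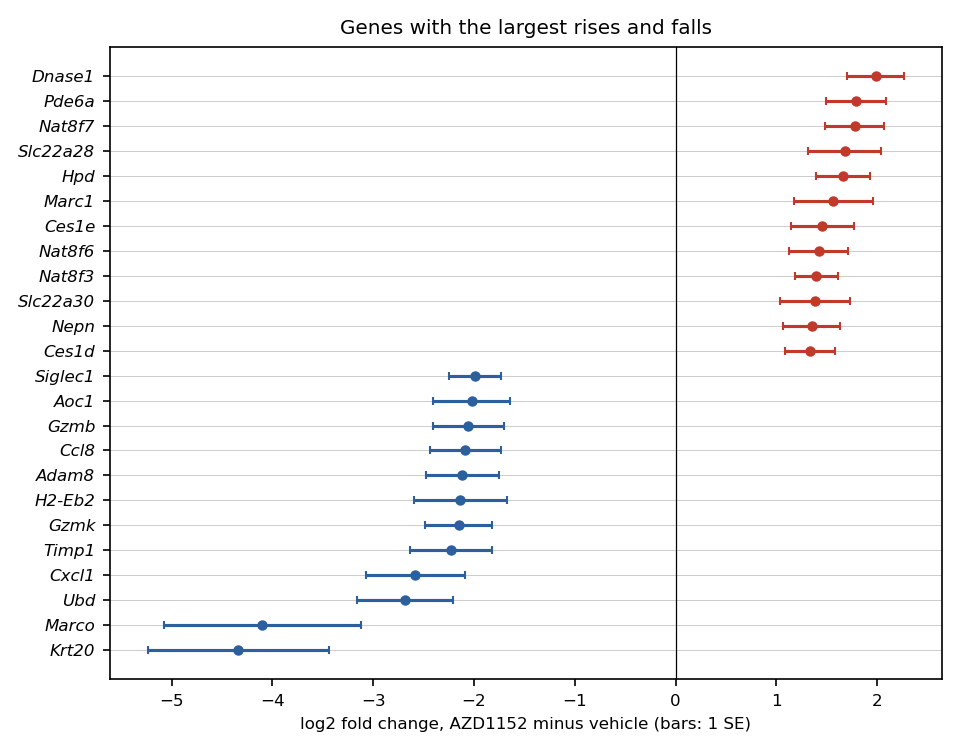
Log2 fold change, AZD1152 minus vehicle (horizontal axis), of the 12 genes with the largest rises (red) and the 12 with the largest falls (blue) by the rule for named genes; points are edgeR estimates and bars 1 SE, over 4 AZD1152 and 3 vehicle libraries. Rises ran from 1.33 (Ces1d) to 1.99 (Dnase1) and falls from -1.99 (Siglec1) to -4.34 (Krt20), with the widest bars for Marco and Krt20.

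Among the other lists, fry called those of the circadian clock and of androgen-dependent kidney genes higher, with 1 member of each past the test over all genes and 3 and 2 members with negative estimates. By their Xist and Y-linked counts the mice were female, and androgens were not measured, so the name of the latter list does not show an androgen effect. In the clock list Dbp, a clock output gene that shares exonic positions with Sphk2, rose by 1.11 ± 0.27 on the log2 scale (edgeR adjusted p = 0.0419). Of 15 members 1 passed over all genes, and 5 rose and 1 fell when adjusted over the list alone (median 0.41, fry adjusted p = 0.0432; adjusted p = 0.17 with an estimated correlation). Tef and Per3 had 0.54 ± 0.14 and 0.52 ± 0.14 (edgeR adjusted p = 0.0521 and 0.0592). In the androgen-dependent list Cyp4b1, a cytochrome P450, rose from 978.5 ± 78.03 to 1597 ± 34.9 CPM. Of 9 measured members 1 passed over all genes and 2 when adjusted over the list alone (median 0.55, fry adjusted p = 0.0307; adjusted p = 0.17 with an estimated correlation), and Cyp2e1 and Akr1c21 had 0.90 ± 0.26 and 0.68 ± 0.29. Cholesterol synthesis was not called (median -0.13, fry adjusted p = 0.505). Of its 15 measured members Sqle, which encodes squalene epoxidase, was the 1 that fell, over all genes and when adjusted over the list alone (-0.89 ± 0.19, edgeR adjusted p = 0.0278), while Cyp51 had -0.45 ± 0.14. Immediate early genes were not called (median -0.36, fry adjusted p = 0.144). Of 16 members 2 fell over all genes, Zfp36 (-0.64 ± 0.14) and Dusp1 (-0.39 ± 0.09), and 3 when adjusted over the list alone, while Btg2 had -0.65 ± 0.18. In the unfolded protein response list 0 of 15 members passed in edgeR, over all genes or adjusted over the list alone, with 6 at an unadjusted p under 0.05 and 0 called by DESeq2 (median 0.36, fry adjusted p = 0.308). Hsp90b1, Pdia4 and Dnajb9 had 0.39 ± 0.14, 0.36 ± 0.13 and 0.47 ± 0.18. Erythroid cells (4 measured genes), perirenal fat (3), adrenal cortex (2), skeletal muscle (3) and the list of Y-linked and X-inactivation genes (1, Xist) had 0 members past the test in edgeR, over all genes or adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 called by DESeq2. Their medians were 0.51, -0.36, 0.32, 0.23 and -0.19 (fry adjusted p = 0.572, 0.932, 0.661, 0.763 and 0.144). Hbb-bs, Hba-a1 and Alas2 had 0.61 ± 0.40, 0.51 ± 0.40 and 0.51 ± 0.44, and Lipe, Fabp4 and Plin4 0.59 ± 0.29, -0.36 ± 0.23 and -0.43 ± 0.51. Akr1b7 and Star had 0.71 ± 0.50 and -0.07 ± 0.20, Actn3, Myh1 and Mylpf 1.01 ± 0.50, -0.84 ± 0.69 and 0.23 ± 0.40, and Xist -0.19 ± 0.10. Cyp51, Dusp1, Alas2 and Plin4 share exonic positions with Akap9, Ergic1, Apex2 and Hdgfl2, and Hsp90b1 with Gm15344. Without vehicle replicate 2 or 3 or any AZD1152 replicate the clock call was lost, and without vehicle replicate 2 or 3 or AZD1152 replicate 1, 2 or 4 the androgen-dependent call was lost (fry adjusted p = 0.0586 to 0.161 and 0.0695 to 0.0985). Both were also lost with scaling by total counts (fry adjusted p = 0.201 and 0.0867). The calls of Dbp, Sqle, Zfp36 and Dusp1 were lost without 4, 3, 4 and 6 libraries, vehicle replicate 3 and AZD1152 replicate 4 always among them (edgeR adjusted p up to 0.164, 0.0679, 0.112 and 0.161), and that of Dbp also with limma-voom.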

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

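The tests of mitosis against leukocytes and of the tubule against other renal cells were chosen only after the result was seen. Those of GC content, scaling by total counts, time of day and other splits were also written after the gene and list results were seen, with limits set before their own values were. That a value must pass its limit by more than its spread was added to the tests of GC content and scaling after their values were seen, which left both open for the proximal tubule where the limits alone would have excluded them. In each AZD1152 quantity a library was marked where its gap to the nearest of the other 3, divided by the range of the 4, passed the 95% limit of Dixon's test, which chance does in about 1 of 20 groups. Of 166 quantities, many of them related, 12 were marked, and groups of 3 were not tested.

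The mitosis list fell in the treated kidneys, and fewer leukocytes with an unchanged share of cycling cells could account for it, as the mitosis score minus the leukocyte score differed between the groups by 0.10 ± 0.134 (SE; exact permutation p = 0.457). The leukocyte score fell by 1.18 ± 0.196 and the mitosis score by 1.08 ± 0.162 (exact permutation p = 0.0286 each, the smallest possible). After removal of the trend on GC content, length and expression the list median was -0.99 against -1.13 before, so those biases were excluded for this list. A direct action of the drug on cycling cells and a loss of leukocytes could not be told apart, because the tissue was not sorted. Of the 35 splits of the 7 libraries into 4 and 3, 1 had as small a fry p for the mitosis list, the real one (7.0e-04 against 0.021 for the next). That next split kept all vehicle libraries together, and splits that mix the groups do not measure chance alone.

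The proximal tubule, distal convoluted tubule and collecting duct lists rose, and dilution by leukocytes in the vehicle kidneys was tested for the proximal tubule with renal cells that dilution would move alike. The proximal tubule score minus the podocyte and endothelium score differed by 0.50 ± 0.206 (exact permutation p = 0.0286), and the podocyte and endothelium score by 0 ± 0.088, so dilution alone was excluded for the proximal tubule within these markers. With scaling by total counts the mean log2 fold change of the proximal tubule list was 0.35, above a limit of 0.25 by less than the SE of 0.147 of its score, and the list stayed called, so the scaling was left open, and the distal convoluted tubule and collecting duct lists lost their calls (fry adjusted p = 0.0901 and 0.158). After removal of the trend on GC content, length and expression the median of the proximal tubule list went from 0.54 to 0.27, beside a limit of 0.25. That of the collecting duct went from 0.29 to 0.19, so the trend was left open for both lists. It could account for oxidative phosphorylation (0.31 to 0.05) and not for the distal convoluted tubule (0.63 to 0.66). Over all genes the log2 fold change had a Spearman correlation of 0.0048 with GC content and -0.0923 with length. The fit on mean CPM also removes a real change that abundant genes share. A lower median after removal therefore cannot tell a bias from such a change. The mitochondrial share, 8.03% to 9.0% with vehicle and 9.41% to 11.6% with AZD1152, moved with these lists, and whether RNA quality differed was not tested.

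The clock list rose, and a different time of day at collection could not be told from an effect of treatment. The evening minus the morning score differed by 0.72 ± 0.456 (exact permutation p = 0.171), with -0.27 ± 0.244 for morning genes and 0.45 ± 0.233 for evening genes (exact permutation p = 0.457 and 0.143). The labels give no time of collection.

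Of the 35 splits 1, the real one, gave as many as 476 higher and 1 as many as 759 lower genes in edgeR. The other splits gave at most 0 of each. Up to 2650 genes had an unadjusted edgeR p under 0.05 there, against 3912 in the real split. Those 2650 came from the split that put all vehicle libraries with AZD1152 replicate 1. Each other split put both groups into at least 1 of its sets, so a group difference widened the spread within that set. That few genes were called there could hardly have come out otherwise, and these splits do not measure chance alone. For interferon, T cells, macrophages and the proximal tubule 1 split had as small a fry p, the real one (0.000588, 0.0109, 0.00688 and 0.0108, against 0.00956, 0.0378, 0.0184 and 0.045 for the next). The next values all came from splits that kept the vehicle libraries together. For B and plasma cells 6 of the 35 splits had as small a fry p (0.182 in the real split, 0.00185 in the lowest).

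AZD1152 replicate 2 stood apart in the mitochondrial share (0.839 of the range; 11.6% against 9.60 ± 0.178%, mean and SD of the other 3) and in the share of the 10 most abundant genes (0.831; 16.7% against 14.6 ± 0.196%). It was highest for the proximal tubule score (0.9 of the range; 9.76 against 9.50 ± 0.0155 log2 CPM) and AZD1152 replicate 3 lowest for the collecting duct score (0.831; 5.74 against 5.94 ± 0.0193). In log2 CPM, AZD1152 replicate 2 lay lowest for Ubd (0.917 of the range; 1.64 against 4.19 ± 0.122), H2-Eb2 (0.867; -0.23 against 1.64 ± 0.133), Prdm1 (0.91; 1.92 against 2.45 ± 0.0268), Mcm3 (0.871; 2.53 against 2.98 ± 0.035), Cd3g (0.874; 1.70 against 2.38 ± 0.0498) and Cd3d (0.87; 0.72 against 1.499 ± 0.0577). AZD1152 replicate 3 lay lowest for Lig1 (0.836 of the range; 2.57 against 2.86 ± 0.0257) and highest for Cd44 (0.885; 4.04 against 3.54 ± 0.0304).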

How the results depend on the processing

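The number of calls depended on the libraries and the scaling. Every gene called in edgeR kept its sign in every alternative that tested it. That could hardly have come out otherwise, as 1231 of the 1235 called genes had no overlap between the groups. Scaling by total counts, and the list alternatives that processing names as added, were chosen after seeing the data. Scaling by total counts gave 232 higher and 1482 lower genes, DESeq2 950 and 1183, an adjusted p under 0.1 1020 and 1315, and a log2 fold change above 1 in size 38 and 390; RLE, upper-quartile and the other alternatives of scaling, filter and test stayed within 1.5 times the 476 and 759 of edgeR. Without single libraries the counts ran from 60 (without vehicle replicate 3) to 475 higher and from 163 to 619 lower (without vehicle replicate 2). Fewer libraries tested lower the power, and beyond that the cause was not tested for any call lost or turned below. The labels do not say that equal replicate numbers mark anything shared, and residuals of equal numbers correlated at -0.288, 0.209 and -0.119. The replicate block (6 libraries, 3 pairs) gave 64 higher and 148 lower genes and kept 1 of 20 lists, tubular injury. Of the 87 called genes that the rule names, the block kept 34, scaling by total counts 79, no filter 85, the stricter filter all 82 that it tested, limma-voom 81, and RLE, upper-quartile, DESeq2 and TMM without the top genes 87. Without single libraries 30 (vehicle replicate 3) to 73 (AZD1152 replicate 3) of the 87 stayed called.

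With the replicate block the fry adjusted p = 0.114 for mitosis, interferon, chemokines and NF-kB targets, 0.122 for the proximal tubule, 0.153 for DNA replication, cytotoxic lymphocytes, macrophages, MHC class I, complement, matrix, collecting duct, fatty acid oxidation and oxidative phosphorylation, 0.178 for MHC class II, 0.209 for T cells, clock and androgen-dependent genes, and 0.214 for the distal convoluted tubule. It turned podocytes (0.725), skeletal muscle (0.878), Star (0.034 on the log2 scale) and Mylpf (-0.052). Scaling by total counts lost the distal convoluted tubule (fry adjusted p = 0.0901), collecting duct (0.158), fatty acid oxidation (0.18), clock (0.201) and androgen-dependent list (0.0867), and turned podocytes (0.356), endothelium (0.392) and Kdr (-0.036 on the log2 scale). Upper-quartile factors turned endothelium (fry adjusted p = 0.97), the stricter filter endothelium (0.988) and adrenal cortex (0.677), and no filter perirenal fat (0.964), adrenal cortex (0.111) and skeletal muscle (0.666). No filter also called the Y-linked and X-inactivation list (fry adjusted p = 0.0223), where counts of 3 or fewer enter. Camera with an estimated correlation called 0 of 34 lists, with adjusted p = 0.132 for interferon and chemokines, 0.135 for NF-kB targets, 0.14 for mitosis, 0.174 for matrix and fatty acid oxidation, 0.231 for oxidative phosphorylation and 0.17 for the other 13. Camera with the preset correlation added B and plasma cells (adjusted p = 0.000497), the unfolded protein response (0.0426) and immediate early genes (0.0189).

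Without single libraries 4 of the 20 lists stayed called throughout (mitosis, interferon, chemokines and NF-kB targets). The fry adjusted p of the other 16 ran from 0.0162 to 0.0711 for DNA replication, 0.0313 to 0.0909 for T cells, 0.0229 to 0.0711 for cytotoxic lymphocytes, 0.034 to 0.0795 for macrophages, 0.0443 to 0.091 for MHC class II, 0.0217 to 0.0711 for MHC class I, 0.0226 to 0.0968 for complement, 0.0246 to 0.0795 for tubular injury, 0.0436 to 0.112 for matrix, 0.0436 to 0.0795 for the proximal tubule, 0.0231 to 0.101 for the distal convoluted tubule, 0.0231 to 0.0968 for the collecting duct, 0.0443 to 0.105 for fatty acid oxidation, 0.0436 to 0.0711 for oxidative phosphorylation, 0.0229 to 0.161 for the clock and 0.0229 to 0.0985 for androgen-dependent genes. Of the lists not called, neutrophils ran from 0.0448 (called without AZD1152 replicate 3) to 0.511 and the Y-linked and X-inactivation list from 0.0231 (called without vehicle replicate 2) to 0.346. Those that turned were endothelium (0.0436, called lower without vehicle replicate 2, to 0.989), podocytes (0.062 to 0.994), loop of Henle (0.422 to 0.994), perirenal fat (0.397 to 0.998), cholesterol synthesis (0.335 to 0.747), adrenal cortex (0.412 to 0.94) and skeletal muscle (0.492 to 0.962). On the log2 scale Star ran from -0.149 to 0.034, Plin4 from -0.962 to 0.088 and Mylpf from -0.02 to 0.467. Depth put the floor of a gene with 0 counts at 0.176 to 0.204 CPM, and 15774 of 53465 genes had enough counts to be tested.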

Other observations

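Gene families, grouped by the letters that open their symbols, were tested after the data were seen, as 244 families of at least 8 genes among 11164 genes. The test was a one-sided Fisher test adjusted by Benjamini-Hochberg over families and directions. It treats genes as independent, while members of a family can move together in the same mice. Its p-values therefore do not measure the spread between mice. Among other groups that passed for falls were Arhgap, Sh and Pik (Fisher adjusted p = 0.00472, 0.0281 and 0.0281). The families below fell beside markers of T cells and macrophages, whose lists had medians of -1.41 and -0.96. Some called members also belong to lists reported above. Ifi35, Ifi44, Parp14 and Irf7 are in the interferon list, and Cd3d, Cd3g and Cd4 in the T cell list. Those families are therefore not separate from these lists. Of the interferon-inducible Ifi genes 13 of 15 fell (Fisher adjusted p = 5.98e-13), from -0.94 for Ifi35 to -2.10 for Ifi214 on the log2 scale. Of the guanylate-binding Gbp genes 6 of 10 fell (Fisher adjusted p = 0.000237), with Gbp9 at -1.18 ± 0.09 and Gbp8 at -1.80 ± 0.28. Of the Parp genes, which act in ADP-ribosylation, 7 of 12 fell (Fisher adjusted p = 6.42e-05), with Parp14 from 132.5 ± 29.8 to 62.1 ± 9.76 CPM. Of symbols with Irf and a number 5 of 12 fell (Fisher adjusted p = 0.00727), the interferon regulatory factors Irf1, Irf5, Irf7, Irf8 and Irf9. Of the Ms4a membrane proteins 6 of 11 fell (Fisher adjusted p = 0.000428), among them Ms4a6b at -1.59 ± 0.20. Of symbols with Cd and a number 22 of 80 fell (Fisher adjusted p = 9.02e-09), with Cd96 at -2.12 and Cd47 at -0.39. Of symbols with Il and a number, such as interleukins and their receptors, 10 of 43 fell (Fisher adjusted p = 0.00193), with Il10 from 1.005 ± 0.277 to 0.247 ± 0.075 CPM. Members of a family can share reads, and Gbp4, Gbp8 and Gbp9 share exonic positions. Irf5, Irf7 and Irf9 share them with Tnpo3, Phrf1 and Rnf31.

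The families that rose did so beside the proximal tubule list (median 0.54), which holds the called solute carriers Slc34a1, Slc5a2, Slc5a12 and Slc13a3. Among them were the Aldh genes, aldehyde dehydrogenases that act in the breakdown of amino acids and aldehydes. Of these, 7 of 20 were higher (Fisher adjusted p = 0.000123) by 0.48 to 0.53 on the log2 scale. Aldh2 rose from 770.9 ± 65.7 to 1082 ± 29.97 CPM and Aldh7a1, which shares exonic positions with Phax, from 308.9 ± 32.0 to 444.7 ± 36.8 CPM. Of the Nat genes 5 of 13 rose (Fisher adjusted p = 0.00163), all of the Nat8 group. Of the Ndufa genes of complex I 5 of 14 rose (Fisher adjusted p = 0.00193) by 0.31 to 0.40, and of the cytochrome P450 genes 6 of 41 (Fisher adjusted p = 0.0379) by 0.55 to 1.18, Cyp4a12b the most. Of the solute carriers 27 of 302 rose and 10 fell (Fisher adjusted p = 6.42e-05 for the rise), and their median of 0.06 became -0.09 with scaling by total counts. The medians of all tested Aldh, Ndufa and cytochrome P450 genes went from 0.25, 0.24 and 0.18 to 0.09, 0.10 and 0.02 with that scaling. The oxidative phosphorylation list, which holds Ndufa9, had a median of 0.05 after removal of the trend on GC content, length and expression, against 0.31 before, and the Ndufa genes were not tested for that trend as a family.

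Transcripts of immunoglobulins differed between mice of the same group. They took 0.0766%, 0.474% and 0.591% of the counts in vehicle replicates 1 to 3 and 0.39%, 0.0909%, 0.0122% and 0.0753% in AZD1152 replicates 1 to 4. Ighg2b had 341.5 ± 337.2 CPM (SD, n = 3) with vehicle and 51.1 ± 53.5 CPM (SD, n = 4) with AZD1152, and Jchain, which joins polymeric antibodies, 484.3 ± 336.5 and 177.4 ± 204.1 CPM, and neither passed the test in edgeR.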
